A study of Homo sapiens with 3 samples.

How the data were processed

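Single-cell RNA sequencing was performed on human pluripotent stem cells that carried the CALIPERS reporter, a fluorescent reporter of the cell cycle, after differentiation into several lineages or into cardiac organoids. Per the labels, 3 libraries were made from 1 multiplexed run with the 10x Genomics 3' v3.1 chemistry. One library held cellular RNA, another held the oligonucleotides that tag the cells of each multiplexed sample, and the last held reporter transcripts amplified from the same material. Each library was given its own group from its title, so no group of libraries had replicates.

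The deposited material used here consisted of a list of cell barcodes, a list of features and the table that named the multiplexed samples when they were aggregated. Cell Ranger was used, per the submitters' processing notes, and the aggregation table points to separate outputs for each multiplexed sample. The Cell Ranger version, the genome build, the annotation, the treatment of doublets and any equalisation of depth between samples are not given in the sources used here. The barcode list is named as filtered, so its entries were taken as the cells called by the authors. These files carry names and identifiers and no measured expression value. Expression levels, UMI numbers, cell types, cell cycle phases and reporter transcript levels were therefore not analysed here, and sequencing depth per cell is unknown.

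Each of the 10435 barcode entries consists of 16 bases and the number of its multiplexed sample. The aggregation table gives the same numbers beside the names Germ_layers, Cardioid_early and Cardioid_late, and cells were assigned to samples through that pairing. Cells were counted per sample with exact 95% Poisson intervals, and shares were given exact 95% Clopper-Pearson intervals. Ratios of cell numbers were given intervals converted from the exact binomial interval of the matching share. The limit that 0 cells allow was taken as 3 cells of the sample's total, an approximate one-sided 95% limit, unlike the two-sided intervals. All of these intervals and limits cover counting error only. Each multiplexed sample occurs once, so there was no test between samples, because cells are not replicates.

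Barcode sequences listed under more than 1 sample were counted. For reference, barcodes were drawn 10000 times for each sample from a separate well (random seed 1), with equal chances for every entry of the barcode list of this chemistry. The size of that barcode list was taken from knowledge of the kit and not from the files. The counting of shared and near-identical barcodes was tested on simulated data with planted pairs before use. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

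The feature list was searched for 14 marker lists with 110 different genes, all fixed before the data were examined. The lists covered pluripotency, ectoderm and neural cells, mesoderm, endoderm and liver, cardiomyocytes, endothelium, fibroblasts and epicardium, smooth muscle and pericytes, and blood. Others covered stress and RNA quality, G1/S, G2/M and quiescence. The last was written for genes whose protein fragments are used in fluorescent cell cycle reporters, though not every member is the source of one. The genes named in the text are the first 3 members of each list as written, together with members that were absent by symbol or listed under more than 1 identifier, and every reporter feature. One gene that this rule names is not reported here. Reporter features were recognised by the words CALIPERS or FUCCI or by a fluorescent protein name. The symbols of 12 Ensembl genes contain such letters within a longer name, and these were not counted as reporter features. Current symbols were taken by identifier from a gene name table, which held 36366 of the 36601 Ensembl identifiers, and older symbols were taken from RefSeq synonyms (GRCh38.p14). No coordinates are given because the build behind the feature list is not given in the sources used here.

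The alternatives left out shared barcodes or barcodes within 1 mismatch of another, changed the denominator of the shares, replaced the sum of the organoid samples by their median, counted near-identical barcodes as the same, matched older symbols, and recognised reporter features by type or identifier. Alternatives that needed expression counts were not run.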

Results

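The data described a single multiplexed run of single-cell RNA sequencing on human pluripotent stem cells with the CALIPERS cell cycle reporter. The run combined cells differentiated towards several lineages with cardiac organoids, which are self-organising cultures of heart cell types. The cells fell into 3 multiplexed samples, named Germ_layers, Cardioid_early and Cardioid_late, and the barcode list held 10435 cells in all. From the names alone, Germ_layers was read as the differentiated lineages and both cardioid samples as the cardiac organoids. The lineages and time points that each sample held are not given in the sources used here. Each sample occurred once, so its numbers had no replicate error and were given counting intervals only. Expression values were not analysed here, so the results concern how many cells of each sample were retained and which genes and reporter features the count table was set up to hold.

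The first comparison asked how the retained cells were divided between the differentiated lineages and the cardiac organoids. The Germ_layers sample held 3811 cells (exact 95% Poisson interval 3691 to 3934). The early cardioid sample held 3437 cells (3323 to 3554), and the late cardioid sample held 3187 cells (3077 to 3300). These numbers corresponded to 36.5% of all cells for Germ_layers (exact 95% Clopper-Pearson interval 35.6 to 37.5%), 32.9% for early cardioids (32.0 to 33.8%) and 30.5% for late cardioids (29.7 to 31.4%). Both cardioid samples together supplied 6624 cells, or 63.5% of the total (62.5 to 64.4%).

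**Figure D1:**
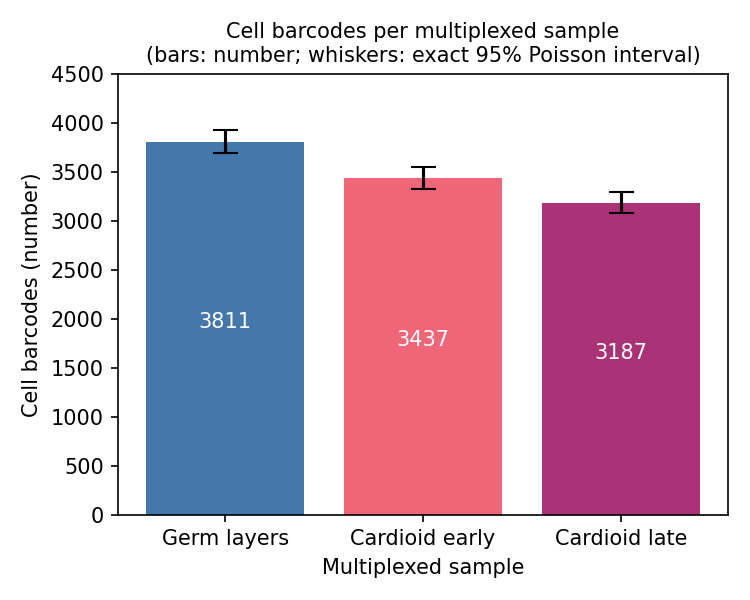
Number of cell barcodes (y axis, linear, from 0) in each of the 3 multiplexed samples (x axis), with whiskers for the exact 95% Poisson interval of counting error. The samples lie between 3187 cells for late cardioids and 3811 cells for Germ_layers, and each bar stands for 1 sample without replicates.

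Early cardioids were represented by 1.08 times as many cells as late cardioids (95% interval 1.03 to 1.13). Germ_layers exceeded early cardioids 1.11-fold (1.06 to 1.16) and late cardioids 1.20-fold (1.14 to 1.25). Against both cardioid samples combined, the ratio of Germ_layers cells was 0.575 (0.553 to 0.599). Against the median of the cardioid samples the ratio was 1.15, so whether the lineages or the organoids had more cells depended on whether the organoid samples were summed. These intervals exclude equal numbers as far as counting error goes, but with 1 sample of each kind the spread between cultures was not measured. Loading, capture and the assignment of cells to samples also set cell numbers, so these ratios describe the list of retained cells and not the cultures. Every listed barcode carries a sample number, so any cell of the run left without an assignment is not counted here. The cells named Germ_layers carried that single name, and the barcode list does not divide them further.

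The number of cells limited what shares could be seen within each sample. For a cell type with 0 cells observed, the approximate one-sided 95% upper limit would be 0.0787% of Germ_layers cells. It would be 0.0873% of early cardioid cells and 0.0941% of late cardioid cells.

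The second comparison concerned barcodes shared between samples. Assigning the cells of 1 multiplexed run to samples gives each barcode to at most 1 of them, so an absence of shared barcodes is fixed by that processing and does not test whether the samples were separated correctly. All 10435 barcode sequences were different, and 0 of them were listed under more than 1 sample. Samples drawn at random from separate wells shared a mean of 5.31 barcodes (95% of draws between 1 and 10), and 45 of 10000 such draws shared none. That reference rests on an assumed barcode list in which every entry is equally likely.

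The third comparison concerned the features against which transcripts were counted. The feature list held 36614 entries, made up of 36601 genes with Ensembl identifiers, 1 reporter feature and 12 multiplexing oligonucleotides. The reporter feature was named Fucciplex and was typed as gene expression, like the endogenous genes. No feature carried the name CALIPERS, although the label of the amplified library uses that name, and the labels of both other libraries use Fucciplex as the name of the cell line. The reporter was entered as a single feature, so a count for it would not distinguish parts of the construct. The multiplexing features ran from CMO301 to CMO312, which is more than the 3 samples, and the files used here do not pair an oligonucleotide with a sample.

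All listed germ layer and pluripotency markers were present as features. The 10 pluripotency genes began with POU5F1, NANOG and SOX2, the core transcription factors of pluripotent cells. The 10 ectoderm and neural genes began with PAX6 and SOX1, transcription factors of the neural lineage, and NES, an intermediate filament of neural progenitors. The 8 mesoderm genes began with TBXT and MIXL1, transcription factors of the primitive streak, and MESP1, a transcription factor of early cardiac mesoderm. The 9 endoderm and liver genes began with SOX17, FOXA2 and GATA6, transcription factors of the endoderm. Presence in the list says that a gene could be counted and says nothing about its expression. With 36601 Ensembl genes in the feature list, finding a marker list in full does not set its genes apart from other genes.

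The listed markers of heart and other cell types were complete as well. The 10 cardiomyocyte genes began with TNNT2, cardiac troponin T, and MYH6 and MYH7, the cardiac myosin heavy chains. The 8 endothelial genes began with PECAM1 and CDH5, adhesion molecules of endothelial junctions, and KDR, a receptor for vascular endothelial growth factor. The 8 fibroblast and epicardial genes began with the collagen genes COL1A1 and COL3A1 and with DCN, a matrix proteoglycan. The 6 smooth muscle and pericyte genes began with ACTA2, TAGLN and MYH11, which encode contractile or actin-binding proteins of smooth muscle. The 6 blood genes began with PTPRC, the leukocyte antigen CD45, and with HBA1 and HBE1, which encode globins. The 7 stress and RNA quality genes began with FOS and JUN, immediate early transcription factors, and HSPA1A, a heat shock protein. The list also held 13 mitochondrially encoded genes.

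The cell cycle genes were found by symbol except for 1 member of the reporter list. All 10 G1/S genes were present, beginning with CCNE1 and CCNE2, which encode cyclin E, and MCM2, a subunit of the replicative helicase. All 10 G2/M genes were present, beginning with CCNB1 and CCNA2, which encode mitotic and S-phase cyclins, and CDK1, a cyclin-dependent kinase. All 6 quiescence genes were present, beginning with CDKN1A, CDKN1B and CDKN1C, which encode inhibitors of cyclin-dependent kinases. Of the 7 genes in the list written for fluorescent cell cycle reporters, 6 were found by symbol. Not every member of that list is the source of a protein fragment used in such reporters. The 6 included CDT1 (ENSG00000167513), a replication licensing factor, GMNN (ENSG00000112312), its inhibitor geminin, and SLBP (ENSG00000163950), which binds histone mRNA. The endogenous genes and the Fucciplex feature were separate entries. Across all 14 lists, 109 of 110 different genes were found by symbol, and 0 of the 109 were listed under more than 1 identifier.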

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

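Leaving out barcodes listed under more than 1 sample, or within 1 mismatch of another, removed 0 cells, so the cell numbers were the same by construction and these settings are not evidence of stability. Counting barcodes within 1 mismatch as the same also left 0 shared barcodes, where random sequences would give 0.405 such pairs between samples. That reference takes every sequence as equally likely, while the barcodes come from a fixed list, so the comparison decides nothing. With Germ_layers left out of the denominator, the share of early cardioids moved to 51.9% and that of late cardioids to 48.1%, because fewer cells were counted in the total. The ratio of Germ_layers to organoid cells moved from 0.575 to 1.15 when the median of the organoid samples replaced their sum, which follows from dividing by 1 typical sample in place of both. Matching older symbols raised the marker genes found from 109 to 110 of 110. Recognising reporter features by type or by an identifier that is not from Ensembl gave 13 features in place of 1, because the 12 multiplexing oligonucleotides were then included. Other settings for summed counts and for the reporter transcript need expression counts and were not run. With each sample occurring once, there were no replicates to leave out in turn and the spread between cultures stays unmeasured. No paired analysis was possible because the libraries had no replicates and no test between samples was made.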

Other observations

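Many histone genes stood in the feature list under older names. Whether their transcripts were captured was not analysed here. The list held 71 genes whose names begin with HIST, such as HIST1H4C, now named H4C3. Of these, 69 had an entry in the gene name table, and all 69 had a different current symbol there. A search of the list with current symbols would miss these 69 genes, while a search by Ensembl identifier would not. In the whole list, 1907 genes had a different current symbol, and for a further 11045 the table gave the identifier in place of a symbol. The HIST names were chosen for this count after the list was seen.

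Among all Ensembl genes, 10 symbols were listed under 2 identifiers each: ARMCX5-GPRASP2, CYB561D2, GGT1, GOLGA8M, HSPA14, LINC01238, LINC01505, MATR3, TBCE and TMSB15B. They were chosen after the list was seen. None of them belonged to a marker list, and a table merged by symbol would add their entries together.

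From the cell numbers alone, 66.5% of random pairs of retained cells came from different multiplexed samples and 33.5% from the same sample. If each sample carried a single tagging oligonucleotide, only the first kind of pair would be marked as a mixture when cells are captured together. The pairing of oligonucleotides with samples is not given in the sources used here, so that condition was not checked. This is a calculation from the sample sizes, and the number of doublets in the run was not measured.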
